A study of Homo sapiens with 18 samples.

How the data were processed

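Total RNA from hCMEC/D3 cells, an immortalised human brain microvascular endothelial line, was hybridised to Agilent single-colour miRNA arrays. Per the labels' protocols, 100 ng of total RNA was labelled with pCp-Cy3, and RNA quantity and quality were checked before labelling. The 18 arrays fell into 6 groups of 3, untreated or given TNFα and IFNγ for 2, 6 or 24 h. Per the file headers, the scans were read with Agilent Feature Extraction 10.5.1.1, which gave a background-subtracted processed intensity for each spot. The deposited value table held this processed intensity averaged per feature and differed from the scanner values by at most 0.497%. The authors also deposited a table of intensity per miRNA, equal to the Feature Extraction total gene signal with values under 1 set to 1. A further table deposited by the authors held log2 values, equal on 17 of 18 arrays to the log2 of that total signal minus a constant per array. In that log2 table, the offset of the array of control 24 h replicate 3 varied between miRNAs (SD 0.376), and the reason is not given.

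Each array held 15739 spots, of which 15024 carried 2689 probes for 851 human and 88 viral miRNAs. Control spots and spots with an outlier flag were left out, and the remaining spots of each probe were averaged. Each array was scaled to its 75th percentile, taken over the 236 probes detected on all 18 arrays because most probes were dim. A probe counted as detected on an array where more than 50% of its spots were well above background. Scaled intensity was then floored at 14.4, the median over arrays of the first percentile of spots well above background, and converted to log2. Each miRNA was represented by its probe with the highest mean. The 192 human miRNAs detected on all 3 arrays of at least 1 group were tested, and 630 were detected on no array. No saturated spot was met. Between 13.7% and 18.8% of the spots of an array lay well above background, and the number of arrays limits the precision. Where a miRNA was not well above background on any array of a group, the fold is given as a lower bound. The bound sets the mean of the bright group against, per array, the higher of the dimmest signal well above background and the signal of the dim probe.

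The log2 values were fitted with limma 3.58.1 in R 4.3.3, with a mean per group and no other term, leaving 12 residual degrees of freedom and a prior of 2.35. Files were read with the R packages jsonlite 2.0.0 and data.table, version 1.17.8. Cytokine arrays were set against control arrays at 2, 6 and 24 h and on average over the times. F tests asked whether the response differed between the times and whether controls differed between the times. P-values are two-sided and adjusted by the Benjamini-Hochberg method within each comparison, with a threshold of 0.05. Changes are cytokines minus control on the log2 scale, with the standard error of the fit.

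The tests, the miRNA lists and the rule for which miRNAs are named were fixed before the data were examined. Named were the 12 largest rises and falls at each time and the 10 on average, all past the threshold with every pair in a single direction. To these came the 8 smallest p-values of each F test, up to 4 members of each list, and a fixed set around miR-155. The lists were inflammation-induced miRNAs, miRNAs reported after TNF in endothelial cells or at the blood-brain barrier, interferon-associated miRNAs, and endothelial and angiogenic miRNAs. Further lists were the let-7 family, the miR-17-92 and paralogous clusters, the miR-23-27-24 clusters, the miR-29 and miR-30 families, p53-linked miRNAs and the imprinted 14q32 cluster. Markers of other cell types covered epithelial, blood, mesenchymal, neural, and pluripotent or liver cells. A list of GC-rich probes, often raised on miRNA arrays when RNA is degraded or scarce, served as a sign of RNA quality. The 9 lists with at least 5 tested members were tested with camera from limma at a preset correlation of 0.01, adjusted over 27 tests of list and time.

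The labels call same-numbered samples of a time pairs, without saying what a pair shares. The pair codes end in the letter A, C, E or F, and these letters recur between the times, C at 2, 6 and 24 h. What a letter stands for is not known. If it marks shared material, the 9 pairs are not all separate. The letter block, an alternative fit, includes a term for it. As a check, the correlation of deviations from the group means was over 0.1 in 8 of 9 pairs, with the lowest at 0.0583 for replicate 2 at 6 h and the highest at 0.684 for replicate 3 at 24 h. Slides 1 and 2 held both treatments at each time, and slide 3 held only the replicate 3 pair at 24 h. The label of control 6 h replicate 1 gives its time as 2 h in a single field and as 6 h in its title and description, and 6 h was used.

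The procedure was tested on 20 simulated data sets of the same 192 miRNAs. At 24 h it recovered 91.1% of simulated changes of log2 size 1, 68.6% of size 0.5 and 27.5% of size 0.25, with 5.42% of calls false. The changes were simulated on the 24 h cytokine arrays only, so their average over the 3 times was smaller than the sizes named. For the same 24 h sizes, the difference between times recovered 80.0%, 45.0% and 8.57%, and the average 70.4%, 28.2% and 3.57%. With no change simulated, 2 of 3840 miRNAs were called at 2 h, 3 of 3840 at 6 h and 0 of 3840 between control times. A list shifted by 0.5 was called in 20 of 20 data sets. The simulated noise was normal and independent between miRNAs and between arrays, with no pair effect, scaling or floor. These shares therefore hold under those conditions only, and do not test the preset correlation on lists whose members are correlated.

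Alternatives covered normexp background correction with an offset of 50, other scalings, floors, filters and summaries, the deposited tables, pair, slide and letter blocks, array weights, an intensity trend, and each array left out in turn. A scaling took the percentile over all probes. At most 18.8% of the spots of an array lay well above background, so that percentile is expected to fall among dim probes. Viral probes were kept out of the comparisons. Neighbouring miRNA genes were taken from a reference gene table of assembly GRCh38.p14, in which 155 of the 192 tested miRNAs matched a single gene.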

Results

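Inflammatory cytokines open the blood-brain barrier, and the series asked how they alter miRNAs, short RNAs that lower the output of the mRNAs they pair with, in brain endothelium. Its title singles out miR-155, an immune-regulated miRNA made from the BIC transcript. hCMEC/D3 cells were left untreated or given TNFα and IFNγ, cytokines released by activated immune cells, for 2, 6 or 24 h, with 3 arrays in each of the 6 groups. The endothelial miRNAs miR-126 and miR-126* were detected on all 3 arrays of every group. By contrast, all 12 epithelial markers, miR-203 among them, were below detection on every array. The same held for 9 of 10 blood cell markers, 12 of 14 mesenchymal markers, 14 of 18 neural markers and 15 of 16 pluripotent or liver markers. An asterisk marks the passenger arm of a hairpin, usually the less abundant strand. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

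After 2 h of cytokines, the response was small and lay mostly in passenger arms. miR-21*, the partner of the stress-induced miR-21, rose 3.42-fold (log2 change 1.78 ± 0.13 SE, n = 3 per group). miR-155* rose at least 3.24-fold from below detection (1.74 ± 0.15), and miR-29b-1* rose 2.06-fold (1.04 ± 0.15), with the control detected on 2 of 3 arrays. miR-30c-2* fell by 0.65 on the log2 scale (± 0.10), or 1.57-fold. In all, 6 of 192 miRNAs changed, 5 higher and 1 lower, each in 3 of 3 pairs, and 5 of the 6 were passenger arms (limma, adjusted p from 3.30e-07 for miR-21* to 0.0336 for miR-132). The smaller rises were miR-132, induced by CREB signalling (0.39 ± 0.10), and miR-20a* (0.26 ± 0.05, at least 1.16-fold). The split was 2 higher and 0 lower under normexp and 3 and 0 with no scaling. Under normexp miR-29b-1* (0.18), miR-20a* (0.03) and miR-30c-2* (-0.29) did not pass, nor did miR-29b-1* with the floor doubled (0.19) or miR-30c-2* with no scaling (-0.49). miR-20a* also failed under all-probe scaling (0.16), no scaling (0.35), the floor doubled, the pairs with the slide as blocks and only the 2 groups compared. miR-132 failed under every other scaling but total gene signal, with the floor doubled, with no filter and with the mean over probes. With the pairs as a block, miR-132 no longer passed (adjusted p = 0.0633, or 0.101 with the slide as well), its change was -0.01 under normexp, and its adjusted p reached 0.245 without control 2 h replicate 1. It also failed without control 2 h replicate 2 or 3 (0.0587 and 0.0550), cytokine 2 h replicate 1 or 3 (0.132 and 0.172), control 6 h replicate 1 or 2 (0.0525 and 0.0515) or control 24 h replicate 2 (0.0526).

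miR-155 itself stood at 0.45 ± 0.14 (1.37-fold) at 2 h, higher in 3 of 3 pairs but short of the threshold (limma, adjusted p = 0.131). It passed with the pairs as a block (adjusted p = 0.0499), and also without cytokine 24 h replicate 2 (0.0269) or 3 (0.0186). Over 22 alternatives other than leaving out single arrays, its adjusted p ran from 0.00196 to 0.992, and 6 passed. Within slides 1 and 2 its change was 0.48 and 0.43, and with the slide as a block 0.45. A second probe for miR-155, also detected on every array, changed by only 0.19 at 2 h, against 0.45 for the probe used.

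Among the lists at 2 h, inflammation-induced miRNAs were called up (camera, adjusted p = 7.23e-08, and adjusted p = 8.71e-04 with an estimated correlation). miR-21*, miR-155* and miR-132 rose, none fell, and 11 of 14 did not pass; adjusted over the list alone, 4 rose, with miR-155 the addition. The mean shift of this list was 0.38, against 0.42 and 0.35 within slides 1 and 2 and 0.37 with the slide as a block. Its median was only 0.14, with miR-21* and miR-155* changed most, and their guide arms are counted as further members. The miR-17-92 clusters, linked to proliferation, shifted by a mean of 0.08 (0.06 and 0.09 within slides 1 and 2, 0.05 with the slide as a block). Their call (adjusted p = 0.0481) was lost with an estimated correlation (adjusted p = 0.282 with an estimated correlation) and with the slide as a block (0.0753). It was also lost without control 2 h replicate 1 (0.106), 2 (0.05002) or 3 (0.0651), cytokine 2 h replicate 1 (0.0634) or 2 (0.0983), control 6 h replicate 2 (0.0504) or control 24 h replicate 1 (0.0516). Only miR-20a* rose in it, with miR-17* at 0.23, miR-20a at 0.09 and miR-18b at 0.09. The other 7 lists tested were not called at 2 h, and their only members past the threshold were miR-132, miR-29b-1* and miR-30c-2*; adjusted over the list alone, 1 interferon-associated miRNA rose, and 1 rose and 2 fell in the miR-29 and miR-30 families.

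By 6 h the guide strand of miR-155 had joined its passenger. miR-155 rose 4.26-fold (2.09 ± 0.14, n = 3 per group), and miR-155* rose at least 4.97-fold (2.34 ± 0.15). miR-21* stood 3.62-fold above control (1.86 ± 0.13) and miR-29b-1* at least 2.77-fold (1.48 ± 0.15). miR-146b-5p, a feedback inhibitor of NF-κB signalling, rose 1.77-fold (0.82 ± 0.17) from detection on 1 of 3 control arrays to 2 of 3 cytokine arrays. Its call was lost with the floor doubled (0.09), under normexp (0.35), with no scaling (0.62), with no filter and with only the 2 groups compared. The passenger arms miR-30c-2*, miR-30a* and miR-30e* of the miR-30 family fell by 0.92 (± 0.10), 0.45 (± 0.08) and 0.43 (± 0.09). None of these 3 passed in limma under normexp (-0.14, -0.23 and -0.0049), and miR-30a* also failed with no scaling (-0.67). miR-30e* failed under all-probe scaling, total gene signal, the authors' values, bright control features, the floor halved and only the 2 groups compared.

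In all, 11 of 192 miRNAs changed at 6 h, 8 higher and 3 lower, each in 3 of 3 pairs (limma, adjusted p from 2.74e-08 for miR-155 to 0.0265 for miR-24). The split was 6 and 0 under normexp, 6 and 4 with quantile normalization, and 10 and 2 with bright control features. The remaining rises were miR-886-3p (0.44 ± 0.09), miR-29a (0.34 ± 0.08), known to restrain extracellular matrix genes, and miR-24 (0.24 ± 0.06). All 3 failed under all-probe scaling, no scaling (0.22, 0.13 and 0.03) and the authors' values, and miR-29a and miR-24 also under quantile normalization and total gene signal. miR-29a failed with no filter too, and miR-24 under normexp and with only the 2 groups compared. miR-24 did not pass with the pairs as a block (adjusted p = 0.0775, or 0.0881 with the slide as well), nor without control 6 h replicate 2 (0.146) or 3 (0.0589) or cytokine 6 h replicate 1 (0.118) or 3 (0.0516). miR-29a failed without control 6 h replicate 2 (0.115) or cytokine 6 h replicate 1 (0.0837) or 2 (0.0632). miR-30e* failed without cytokine 6 h replicate 1. miR-21 (0.30 ± 0.11, adjusted p = 0.210) and miR-146a, the other NF-κB-induced brake (0.32 ± 0.24, adjusted p = 0.646), did not pass at 6 h. Without cytokine 6 h replicate 3 both did (0.0229 and 0.00456), with miR-146a then at 0.72, and both did with array weights (0.40 and 0.68). The change of miR-146a differed in sign between slides 1 and 2 (-0.49 and 0.73) and was 0.61, 0.81 and -0.46 in pairs 1, 2 and 3. Within slides 1 and 2, miR-155 changed by 2.04 and 2.10, with 2.08 under the slide block.

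Inflammation-induced miRNAs were again up as a list at 6 h (camera, adjusted p = 1.41e-05, and adjusted p = 0.00349 with an estimated correlation). Of 14 members, miR-155, miR-155*, miR-146b-5p and miR-21* rose and none fell; adjusted over the list alone, 5 rose. Their mean shift was 0.57, with 0.49 and 0.59 within slides 1 and 2 and 0.56 with the slide as a block, and their median was 0.19. Interferon-associated miRNAs also moved up (adjusted p = 0.00565), a call lost with an estimated correlation (adjusted p = 0.124 with an estimated correlation). Of its 6 tested members, miR-155 and miR-29a rose, also when adjusted over the list alone; miR-146a stood at 0.32 and miR-29b at 0.15. The mean shift was 0.51, with 0.42 and 0.53 within slides 1 and 2 and 0.49 with the slide as a block. miR-155 and miR-146a belong to both lists. The other 7 lists were not called at 6 h. In the miR-29 and miR-30 families 2 of 13 rose and 3 fell, and of the miRNAs reported after TNF miR-155 and miR-146b-5p rose; the counts were alike when adjusted over the list alone.

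At 24 h the response had spread to many of the miRNAs tested, with miR-155 at its head. miR-155 rose 10.4-fold (3.37 ± 0.14, n = 3 per group), from a geometric mean scaled intensity of 206 to 2131. The NF-κB brakes followed, miR-146b-5p 7.51-fold (2.91 ± 0.17) and miR-146a 3.08-fold (1.62 ± 0.24). The 24 h controls of miR-146b-5p lay at log2 intensities of 3.94 to 3.97, close to the floor at 3.85, so the size of its rise is tied to the floor. miR-21* rose 5.50-fold (2.46 ± 0.13), and miR-21, linked to cell survival, 1.84-fold (0.88 ± 0.11). miR-21 lost its call under all-probe scaling (0.25), quantile normalization (0.25) and no scaling (0.33). On the other side, miR-30c fell by 2.44 (± 0.42), 5.42-fold, with 2 of 3 cytokine arrays still above background, and by 1.79 without cytokine 24 h replicate 3 and 2.90 without replicate 2. The angiogenic pair miR-23b and miR-27b fell by 1.08 (± 0.10) and 1.16 (± 0.10).

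In all, 114 of 192 miRNAs changed at 24 h, 54 higher and 60 lower, with 21 over 2-fold up and 9 over 2-fold down (limma, adjusted p = 7.38e-11 for miR-155). The count was 86 with only the 2 groups compared, 91 of 851 with no filter and 143 with array weights. Each rise and fall named in this paragraph and the last showed its direction in 3 of 3 pairs. The other large rises were miR-155* (1.99 ± 0.15, at least 3.98-fold), miR-575, miR-572, miR-1202, miR-663, miR-638, miR-1225-5p and miR-1268, between 1.47 and 2.27. All of these but miR-155* are on the GC-rich list that served as a sign of RNA quality. Further large falls were miR-324-5p (-1.39 ± 0.12), miR-31* (-1.33 ± 0.07), miR-361-5p (-1.20 ± 0.07), miR-30b (-1.11 ± 0.22) and miR-128 (-0.999 ± 0.06). miR-532-5p fell by 0.81 (± 0.10), miR-30e* by 0.84 (± 0.09) and miR-582-5p by 1.03 (± 0.20), but normexp turned miR-30e* and miR-582-5p to 0.11 and 0.04 and left miR-532-5p at -0.04 and miR-128 at -0.20, not past the threshold. With the floor doubled miR-30e* was at -0.06 and did not pass. miR-99a fell by 1.20 (± 0.36) with adjusted p = 0.01005, but without slide 3 its change was -0.47 with adjusted p = 0.158, and without control 24 h replicate 3 it was -0.71. It also failed under normexp (-0.12), with the floor doubled, with no filter, with array weights (-0.53) and with only the 2 groups compared. All 61 miRNAs that changed at 24 h and had 2 probes detected on every array showed a single sign in both. Within slides 1, 2 and 3, miR-155 changed by 2.90, 3.54 and 3.67, with 3.37 under the slide block.

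The balance of rises and falls at 24 h depended on the scaling. With the percentile taken over all probes 17 rose and 118 fell, with no scaling 16 and 97, with total gene signal 24 and 97, with the authors' normalized values 23 and 101, with quantile normalization 37 and 70, and with normexp 89 and 29. A scaling to bright control features, chosen after the data were seen, gave 26 and 96. These settings moved the median change of all tested miRNAs by -0.55, -0.45, -0.40, -0.46, -0.10, 0.25 and -0.34, in the same order. Changes are therefore relative to the miRNAs detected on every array.

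**Figure D1:**
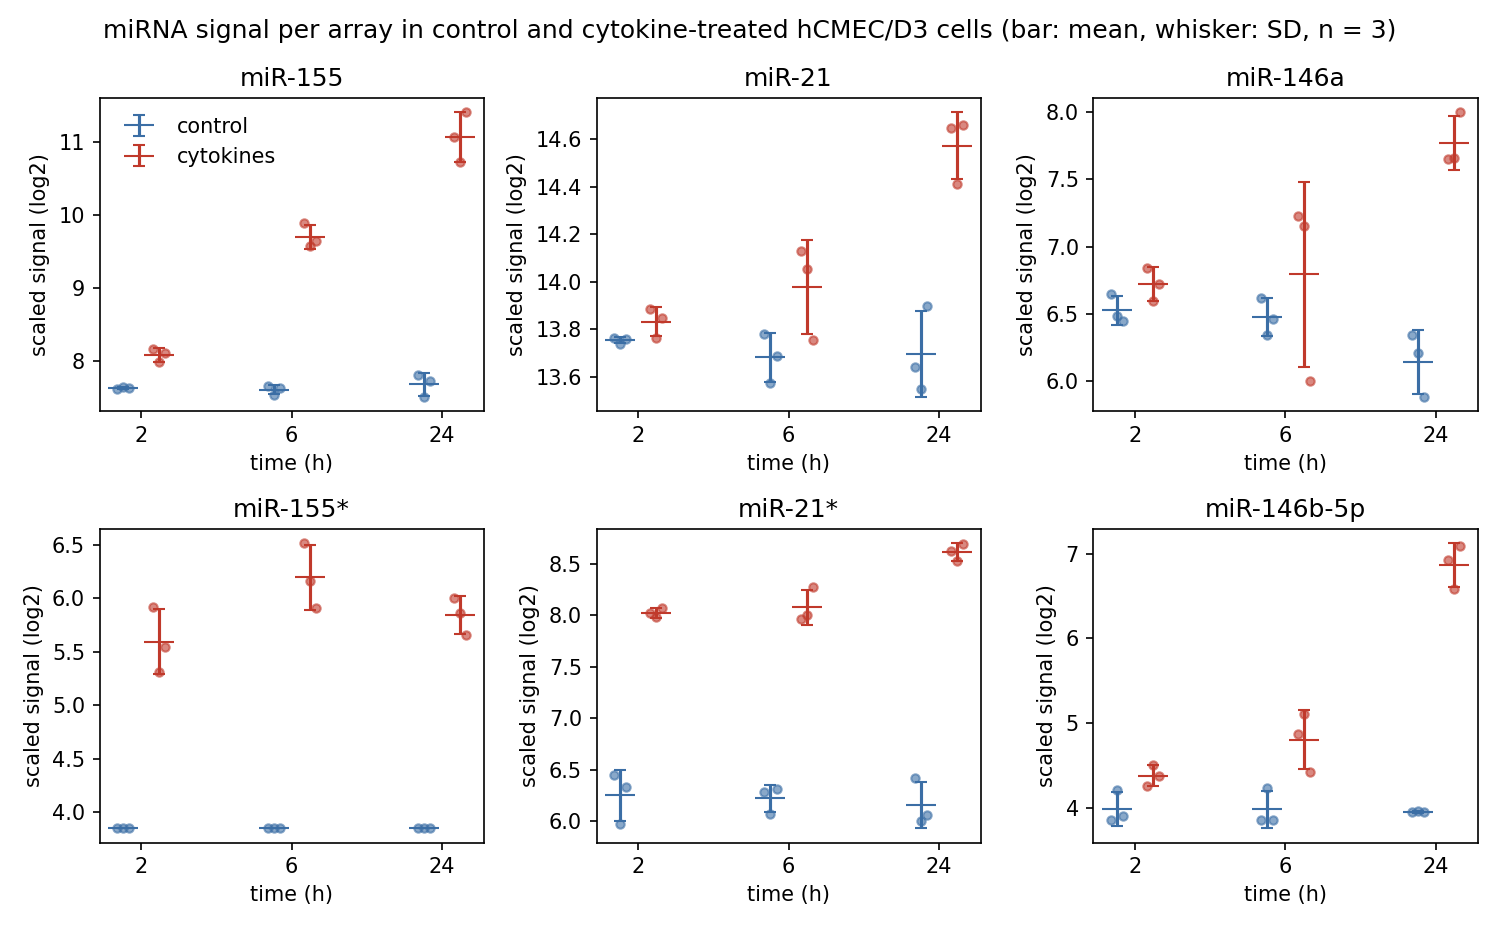
Log2 scaled intensity of 6 miRNAs on each of the 18 arrays at 2, 6 and 24 h, for untreated cells and cells given TNFα and IFNγ, with points for arrays and bars for the mean ± SD of 3. miR-155* and miR-21* already differed at 2 h, whereas miR-155 rose 4.26-fold by 6 h and 10.4-fold by 24 h.

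**Figure D2:**
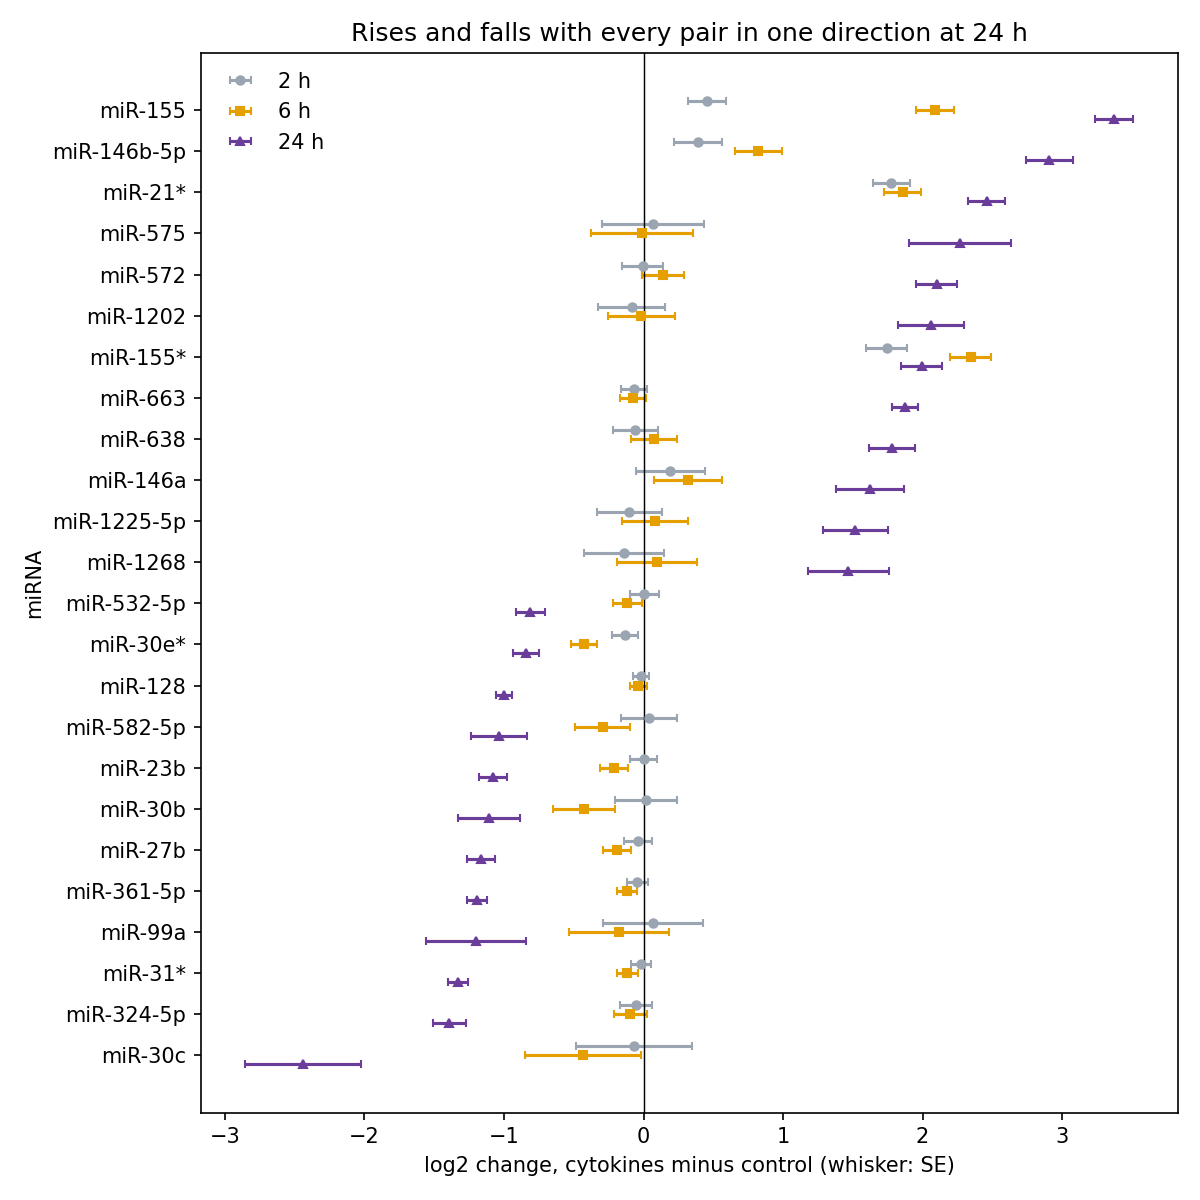
Log2 change, cytokines minus control, at 2, 6 and 24 h for the 12 largest rises and the 12 largest falls at 24 h among miRNAs past the threshold with 3 of 3 pairs in a single direction, with bars for the standard error of the fit (n = 3 arrays per group). Of these miRNAs, miR-155* and miR-21* passed the threshold at 2 h, and miR-155, miR-155*, miR-21* and miR-146b-5p, all higher, and miR-30e*, lower, at 6 h, and normexp turned the 24 h falls of miR-30e* and miR-582-5p to 0.11 and 0.04.

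Of 14 inflammation-induced miRNAs tested, 9 rose at 24 h, 2 fell and 3 did not pass, and the counts were alike when adjusted over the list alone (9 rose, 2 fell). miR-155, miR-146b-5p and miR-21* led the rises, and miR-31* and miR-17* (-0.70, but -0.05 under normexp) fell. The list was called up (camera, adjusted p = 0.0258), but not with an estimated correlation (adjusted p = 0.111 with an estimated correlation) or with the pairs as a block (0.0542) or the slide (0.0518), and its median of 0.54 turned to -0.07 under all-probe scaling. Its mean shift was 0.88, with 0.82, 0.98 and 0.83 within slides 1, 2 and 3 and 0.88 with the slide as a block. miR-31, which targets the adhesion molecule E-selectin, rose by only 0.16 ± 0.06 (adjusted p = 0.0344). It turned to between -0.47 and -0.18 under all-probe scaling, no scaling, total gene signal, the authors' values and the bright control features. It also failed without control 24 h replicate 1 (0.0702) or 2 (0.137) or cytokine 24 h replicate 1 (0.111) or 2 (0.0622), under normexp (0.14), with the pairs and the slide as blocks (0.0506) and with only the 2 groups compared.

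Interferon-associated miRNAs were called up at 24 h at the preset correlation (adjusted p = 0.0481) but not with an estimated correlation (adjusted p = 0.282 with an estimated correlation). Of its members 5 of 6 were higher and miR-29c lower, as also when adjusted over the list alone. miR-29a rose by 0.65 ± 0.08, miR-296-5p by 0.52 ± 0.18 and miR-29b by 0.49 ± 0.12, but these 3 depended on the scaling. With all-probe scaling, no scaling, total gene signal and the authors' values none of them passed in limma, with miR-29a at 0.02, 0.11, 0.21 and 0.17, miR-296-5p at 0.05, 0.08, 0.25 and 0.18, and miR-29b at -0.14, -0.06, 0.13 and 0.11. miR-29b and miR-296-5p also failed with bright control features (0.13 and 0.32). miR-296-5p failed with quantile normalization (0.31), the floor doubled, no filter, without slide 3 and without cytokine 24 h replicate 1 (0.49) as well. The call was also lost with the pairs (0.0786) or the slide (0.0753) as a block, without slide 3 (0.0789), and without any of 11 single arrays. Those were control 2 h replicates 1, 2 and 3, cytokine 2 h replicates 1 and 2, control 6 h replicates 1, 2 and 3, control 24 h replicates 1 and 2 and cytokine 24 h replicate 3, with adjusted p from 0.05002 to 0.0757. The mean shift was 1.07, with 0.91, 1.13 and 1.16 within slides 1, 2 and 3.

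Endothelial and angiogenic miRNAs split, with 5 of 21 higher, 8 lower and 8 not passing, and no call for the list (camera, adjusted p = 0.346). miR-222, which curbs angiogenesis by targeting KIT, rose by 0.71 ± 0.15, as did miR-424 (0.41 ± 0.08) and miR-503 (0.53 ± 0.16), which share a transcript. Their calls depended on the scaling, and miR-222 did not pass under all-probe scaling (0.08), no scaling (0.16), the authors' values (0.28) or with only the 2 groups compared. miR-424 was at -0.21, -0.13 and -0.05 under all-probe scaling, no scaling and the authors' values, and did not pass with quantile normalization (0.20), total gene signal (0.06), bright control features (0.06) or the mean over probes. miR-503 was at -0.10, -0.01, -0.05 and -0.22 under all-probe scaling, no scaling, total gene signal and the authors' values. It also failed with quantile normalization (0.43), bright control features (0.18), the mean over probes (0.16), no filter, only the 2 groups compared and without slide 3 (0.19), and was at 0.26 without control 24 h replicate 3, against 0.69 without replicate 1. miR-126, the endothelial miRNA that restrains VCAM-1, fell by 0.33 ± 0.10 (adjusted p = 0.00792), and hypoxia-induced miR-210 by 0.46 ± 0.09, though miR-210 was at -0.01 under normexp and miR-126 failed with only the 2 groups compared. miR-126* was at -0.34 ± 0.54 (adjusted p = 0.584); it passed with the pairs (0.0179) or the slide (0.00305) as a block and without slide 3 (0.0227), and was 0.37 without cytokine 24 h replicate 3 and 0.08 without control 24 h replicate 1. miR-221, transcribed with miR-222, was at -0.16 ± 0.18 and did not pass; without cytokine 24 h replicate 2 it was -0.41 with adjusted p = 0.0265, and it was 0.10 without cytokine 24 h replicate 3 and 0.10 under normexp. It was called lower under all-probe scaling (-0.78), no scaling (-0.70), total gene signal (-0.55), the authors' values (-0.58) and bright control features (-0.51).

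Of 16 miRNAs reported after TNF in endothelial cells or at the barrier, 7 rose, 6 fell and 3 did not pass at 24 h (camera, adjusted p = 0.378). Their median of -0.04 and mean of 0.51 differed in sign, and the camera direction was up. miR-125a-5p, reported to support barrier tightness, fell by 0.66 ± 0.11. The NF-κB-limiting miR-181b was at 0.08 ± 0.17, turning negative under all-probe scaling, quantile normalization, no scaling, total gene signal, the authors' values and the bright control features. It was also at -0.11 without control 24 h replicate 3 and -0.03 without cytokine 24 h replicate 1, and at 0.21 without control 24 h replicate 1. miR-181a was at -0.25 ± 0.11 (adjusted p = 0.0804) and passed with the pairs as a block (0.0154), with random pair and letter blocks and with the mean over probes (-0.31). It was called lower, and by more, under all-probe scaling (-0.87), no scaling (-0.79), quantile normalization (-0.50), total gene signal (-0.64), the authors' values (-0.75) and bright control features (-0.60). miR-663 belongs both to this list and to the GC-rich one.

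The let-7 family, which promotes differentiation, had 6 of 9 members lower and 3 not passing, among them let-7c (-0.47 ± 0.10) and let-7e (-0.43 ± 0.10). Among those lower, miR-98 turned positive under normexp. The list was not called (camera, adjusted p = 0.105). Of 13 members of the miR-17-92 clusters, 5 fell and none rose (adjusted p = 0.105), with miR-93 at -0.68 ± 0.06 and miR-17 at -0.37 ± 0.09. In the miR-23-27-24 clusters, miR-23b and miR-27b fell and the other 3 did not pass (adjusted p = 0.315); miR-24 was at 0.12 ± 0.06 and turned negative under all-probe scaling, no scaling, total gene signal, the authors' values and the bright control features. It passed as higher with array weights (0.19), with the floor doubled (0.12), without cytokine 24 h replicate 3 (0.17) and without slide 3 (0.20). miR-27a passed as lower under all-probe scaling (-0.79), no scaling (-0.71), total gene signal (-0.61), the authors' values (-0.64), bright control features (-0.52), the mean over probes (-0.36) and array weights (-0.17). The miR-29 and miR-30 families parted, with miR-29a, miR-29b and miR-29b-1* higher, 7 of 13 lower, miR-30c, miR-30b and miR-30a* among them, and no call (adjusted p = 0.346). Their median of -0.29 turned to 0.04 under normexp, and miR-29b-1* failed with the floor doubled (0.29). None of these counts differed when adjusted over the list alone.

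Among p53-linked miRNAs, 0 of 3 passed at 24 h in limma (0 also at 2 and 6 h), with miR-34a at -0.28 ± 0.19, miR-192 at 0.26 ± 0.16 and miR-107 at 0.04 ± 0.07; miR-192 and miR-107 turned negative under all-probe scaling, no scaling, total gene signal, the authors' values and the bright control features, and miR-192 also under quantile normalization. Under all-probe scaling all 3 passed as falls (-0.90, -0.36 and -0.59 in that order). miR-34a and miR-107 also passed as falls with no scaling (-0.82 and -0.51), total gene signal (-0.67 and -0.32), the authors' values (-0.75 and -0.41) and bright control features (-0.63 and -0.32). miR-34a passed without cytokine 6 h replicate 3 too (0.0180), and miR-192 passed as higher under normexp (0.42) and with array weights (0.33). Without cytokine 24 h replicate 3, miR-192 was at 0.16 and miR-107 at -0.0148; miR-107 was just below 0 without control 24 h replicate 2 and at 0.09 without replicate 3. Of the 14q32 list, miR-494 rose by 1.00 ± 0.27, but did not pass under all-probe scaling (0.37), quantile normalization (0.65), no scaling (0.46), total gene signal (0.62) or the authors' values (0.49). From the same list miR-342-3p fell by 0.61 ± 0.12, though normexp put it at 0.09. Markers of other cell types moved apart. The blood cell marker miR-150 fell by 0.82 ± 0.19, in 2 of 3 pairs, and failed with only the 2 groups compared. The mesenchymal markers miR-140-5p and miR-140-3p were at -0.45 ± 0.09 (-0.08 under normexp) and 0.16 ± 0.07, the latter with adjusted p = 0.0489, and miR-140-3p turned to between -0.46 and -0.17 under all-probe scaling, no scaling, total gene signal, the authors' values and the bright control features. miR-140-3p lost its call without any of 14 single arrays, with adjusted p from 0.0505 to 0.171. Those were control 2 h replicates 2 and 3, cytokine 2 h replicates 2 and 3, control 6 h replicates 1, 2 and 3, cytokine 6 h replicates 1 and 2, control 24 h replicates 1, 2 and 3 and cytokine 24 h replicates 1 and 2. Of the neural list, miR-128 fell and miR-7 rose by 0.91 ± 0.16, but miR-7 did not pass under all-probe scaling (0.28), no scaling (0.37) or the authors' values (0.41). miR-338-3p was at -0.09 (0.08 under normexp) and was called lower under all-probe scaling (-0.71), no scaling (-0.63), the authors' values (-0.67) and bright control features (-0.44). It was at 0.04 without cytokine 24 h replicate 2 and -0.26 without replicate 3. miR-137 was at -0.06, or 0.07 without control 24 h replicate 3 and 0.06 without cytokine 24 h replicate 3, and was called higher under normexp (0.26) and with array weights (0.21) and lower under all-probe scaling (-0.69). The pluripotent marker miR-371-5p was at 0.61 ± 0.31 (adjusted p = 0.0999), at -0.01 under all-probe scaling, and passed with the pairs as a block (2.36e-04). It passed too with the slide, letter and random pair blocks, under normexp (0.54), with quantile normalization (0.67), with array weights (0.60) and without slide 3 (0.61). Single arrays moved it from 0.22 without control 24 h replicate 3 to 1.00 without cytokine 24 h replicate 3, and it passed without the latter (0.00458) or control 24 h replicate 1 (0.81, adjusted p = 0.0495).

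GC-rich probes, the sign of RNA quality, were called up as a list at 24 h (camera, adjusted p = 1.41e-05), but not with an estimated correlation (adjusted p = 0.124 with an estimated correlation). Of 26 tested, 17 rose, 1 fell and 8 did not pass, or 18 and 1 adjusted over the list alone, with a median of 0.94. The number of rises depended on the scaling. Among all miRNAs tested, 16 rose with no scaling and 17 with the percentile over all probes, miR-155 among them each time. The count of 17 for the list therefore does not hold under those scalings. miR-572 (2.10 ± 0.15), miR-663 (1.87 ± 0.09), miR-1207-5p (1.45 ± 0.10) and miR-1275 (0.99 ± 0.08) rose, and miR-150* fell by 0.60 ± 0.21. miR-1275 failed with no scaling (0.45). miR-150* was at 0.09 under normexp, and did not pass with no filter, with only the 2 groups compared, without slide 3 (-0.28), or without control 24 h replicate 3 (-0.52) or cytokine 24 h replicate 3 (-0.37). The list's mean shift was 0.91, with 0.93, 0.88 and 0.93 within slides 1, 2 and 3 and 0.91 with the slide as a block, against -0.09 at 2 h and -0.01 at 6 h. On the same arrays the 75th percentile of intensity was 513 ± 105 (SD, n = 3) with cytokines and 739 ± 73.1 in controls. This shift accompanied every group of miRNAs described at 24 h.

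**Figure D3:**
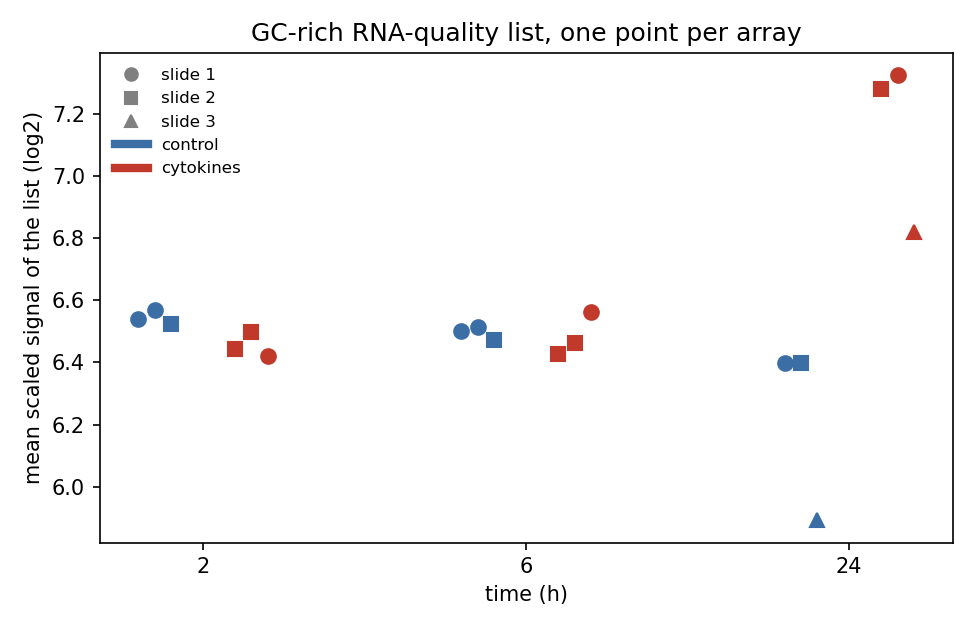
Mean log2 scaled intensity of the 26 tested GC-rich probes on each of the 18 arrays, by group, with the marker showing the slide. With the scaling to probes detected on every array, the list was higher by 0.91 with cytokines at 24 h. The groups differed by -0.09 at 2 h and -0.01 at 6 h.

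Taking the times together, miR-21* (2.03 ± 0.08, n = 9 arrays per treatment), miR-155 (1.97 ± 0.08), miR-146b-5p (1.37 ± 0.10) and miR-29b-1* (1.20 ± 0.08) rose on average. miR-155* stood at 2.03, a size set by the floor, at which all 9 control arrays lay. Some control arrays of miR-146b-5p and miR-29b-1* also lay at the floor, so the sizes of their average rises are tied to it too. Among miRNAs lower in 9 of 9 pairs, miR-30c (-0.98 ± 0.24), miR-324-5p (-0.51 ± 0.07), miR-30a* (-0.48 ± 0.05) and miR-30e* (-0.47 ± 0.05) fell most. In all, 80 of 192 miRNAs changed on average, 34 higher and 46 lower (limma, adjusted p = 2.66e-11 for miR-21*). Smaller rises in 9 of 9 pairs were miR-21 (0.42 ± 0.06), miR-29a (0.35 ± 0.05), miR-132, miR-503 and miR-886-3p, and smaller falls in 9 of 9 pairs miR-361-5p (-0.45 ± 0.04), miR-150*, miR-1181, miR-874, miR-16-2* and miR-15a*. Of the smaller rises, none passed in limma with no scaling, where miR-21 was at 0.22 and miR-29a at 0.15, and only miR-21 passed under all-probe scaling. miR-29a, miR-132 and miR-503 also failed with the authors' values (0.17, 0.14 and 0.03), miR-132 with quantile normalization (0.22) and the floor doubled, and miR-503 with total gene signal (0.12), bright control features (0.21), the mean over probes (0.12), no filter and the pairs with the slide as blocks. Of the falls, miR-1181 and miR-15a* turned to 0.03 and 0.04 under normexp and failed with the floor doubled. miR-30e*, miR-361-5p, miR-150*, miR-874 and miR-16-2* did not pass under normexp either (-0.01, -0.12, -0.05, -0.09 and -0.03), nor miR-150* with no filter. miR-222 was at 0.22 and passed with the pairs as a block (0.00622), as did miR-126* at -0.20 (0.0243), though at 0.04 without cytokine 24 h replicate 3, and miR-181a at -0.12 (0.0407). miR-222 passed too without control 24 h replicate 1 (0.26) or cytokine 24 h replicate 3 (0.29), under normexp (0.20) and with quantile normalization (0.13). miR-181a passed under all-probe scaling (-0.33), no scaling (-0.32), total gene signal (-0.23), the authors' values (-0.30) and bright control features (-0.21). Rises and falls numbered 15 and 96 under all-probe scaling, 11 and 62 with no scaling, 22 and 72 with total gene signal, 19 and 82 with the authors' values, 24 and 60 with bright control features, and 47 and 20 under normexp.

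The response differed between the times for 70 of 192 miRNAs (limma F test, adjusted p = 4.69e-08 for miR-663 and 1.49e-07 for miR-155). From 2 to 24 h the response of miR-155 grew by 2.92 and that of miR-146b-5p by 2.52. The responses of miR-663, miR-572 and miR-1207-5p, all on the GC-rich list, grew by 1.94, 2.11 and 1.61. Those of miR-31*, miR-361-5p and miR-128 changed by -1.31, -1.15 and -0.98. The miRNAs changed at 2 and 6 h shared 4 of 6 and 11, miR-155*, miR-21*, miR-29b-1* and miR-30c-2*, where independent lists would share 0.344 (Fisher's exact test, one-sided p = 8.49e-05, across miRNAs, which are not independent replicates). The 6 h and 24 h lists shared 9, against 6.53 for independent lists (p = 0.104 by the same exact test), and the 2 h and 24 h lists 4 against 3.56 (p = 0.531). All shared miRNAs changed in a single direction.

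Untreated cells gave the background to these changes. Among controls, 0 of 192 miRNAs differed between 2, 6 and 24 h in limma's F test, while 18 had an unadjusted p under 0.05. With the percentile taken over all probes, 51 did differ, with array weights 3 and with the mean over probes 2. Since that percentile is expected to fall among dim probes, whether those 51 reflect the cells is not settled. In controls, miR-155 stayed at log2 intensities of 7.64 ± 0.01, 7.61 ± 0.06 and 7.69 ± 0.16 (SD, n = 3) at 2, 6 and 24 h.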

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

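The tests on the GC-rich list and on other splits were set before their results were seen. The tests on passenger arms and on neighbouring genes, and the splits over all times that part every pair, were chosen after the results were seen.

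The response differed between the times for 70 of 192 miRNAs by limma's F test, which is what singled it out. Of 100 splits drawn, 11, the real split included, gave as many, and the highest other gave 86. All 10 others as large kept the real 24 h groups and rearranged 2 h or 6 h, and the highest split that did not keep them gave 2. Splits that keep those groups retain the difference between them, so this test cannot decide whether the count arose by chance.

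By the same test of the difference itself, the response at 24 h minus that at 2 h was 2.92 for miR-155, 2.52 for miR-146b-5p and 2.11 for miR-572. It was 1.94 for miR-663 and 1.61 for miR-1207-5p. It was -1.31 for miR-31*, -1.15 for miR-361-5p and -0.979 for miR-128.

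Signals also appeared on probes for viral miRNAs, which the comparisons did not use. At 24 h, cytokine arrays exceeded controls by 0.90 for ebv-miR-BART12 (limma, adjusted p = 0.0173 over the 4 tested viral miRNAs and 3 times), by 1.42 for ebv-miR-BART16 (0.00313) and by 0.74 for kshv-miR-K12-3 (0.0111). The fourth, ebv-miR-BART13, was at -0.06 (adjusted p = 0.953), and 80 of the 88 viral miRNAs were detected on no array. These values are given only with the scaling to probes detected on every array, since the alternatives were not run on viral probes. The log2 scale factor, by which they were divided, differed by -0.543 between the 24 h groups, so their sizes are tied to the scaling. Cross-hybridisation was not tested.

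The number of miRNAs changed was set against other splits of the same arrays. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Only 1 split, the real one, reached each count, with 6 at 2 h against 2 for the highest other, 11 at 6 h against 0, and 114 at 24 h against 21. The highest other that parted all 3 pairs gave 0 at each time, and a split by slide gave 0 at 2 h and 0 at 6 h. For the average, 1 of 100 splits, the real one, gave 80, with 62 for the highest other. That other kept the real 24 h groups, and the highest split that did not keep them gave 1. This argues against chance for a count carried mainly by 24 h, and does not bear on 2 or 6 h alone. For the lists, 3 of 100 splits, the real one included, gave as many as 7 calls, with 7 for the highest other. That share is under 0.05, which argues against chance for that count at the preset correlation only. With an estimated correlation 2 calls were left, for which no splits were run, and with the pairs as a block 5 of the 7 were kept. The 2 other splits with 7 both rearranged the 24 h groups. These splits took no account of the pairs. Of 100 splits that parted all 9 pairs, the real one included, 2 gave as many list calls (highest other 7), 2 as many changes on average (highest other 81) and 17 as many differing in response (highest other 91). The others as large all kept the real 24 h groups, and the highest that did not gave 6, 3 and 3. For the control times, 100 of 100 splits gave at least the real count of 0 (limma, 18 at an unadjusted p under 0.05, and 51 with the percentile over all probes, 3 with array weights and 2 with the mean over probes), with 1 for the highest other, so nothing is excluded.

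GC-rich probes were raised by a mean of 0.91 at 24 h, on the arrays that also had the lower 75th percentile of intensity. For lower labelled signal, the slope of the scaled list on the scale factor was taken within the groups at 2 and 6 h. It predicts a shift of 0.0178 (95% interval -0.0987 to 0.134), below the 0.456 that would account for 50% of it. This argues against lower labelled signal alone only if that slope also holds at 24 h, which was not tested. The log2 scale factor, by which values were divided, differed by -0.543 between the 24 h groups. The size of 0.91 is therefore tied to the scaling. GC content was tested with a line fitted on the 166 other miRNAs, after which the list's median stood at 0.940 instead of 0.935 (95% bootstrap interval 0.418 to 1.36). That interval, which carries the spread among the list's members, reaches below 0.468, so the test as set could not decide. The line itself was nearly flat, with a change of 0.0295 per 10% of GC and Pearson's r of 0.0488 among the other miRNAs. RNA degradation and a response to the cytokines both stay open, as untested. A candidate explanation that involves RNA quality on the 24 h cytokine arrays may therefore still apply to miR-575, miR-572, miR-1202, miR-663 and miR-638, but no such explanation was tested for miR-155 or the miR-146 pair, which are not on the list.

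Passenger arms changed at 2 h before their guide arms passed the test, in 5 hairpins of which 0 guides passed at 2 h and 4 changed the same way at 24 h, with miR-20a opposite to miR-20a*. That 0 depends on the fit, since the guide miR-155 passed at 2 h in 6 of 22 alternatives, the pairs as a block among them. Compression of bright guide probes is argued against, since the dimmer probe of each guide changed by a median of 0.0869 of the change of its passenger, with 0.343 the highest of 5. The change of the passenger at 2 h and that of the guide at 24 h correlated over all 18 hairpins with both arms tested (Spearman's rho 0.655, permutation p = 0.00407, Pearson's r 0.795, permutation p = 8.00e-05). Without the 2 hairpins farthest out, r was 0.638 and rho 0.535 (permutation p = 0.0350), across miRNAs, which are not independent replicates. New transcription that shows first in the short-lived strand may account for this, a hypothesis found and tested on the same data.

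miRNAs from neighbouring genes changed alike at 24 h, for example miR-23b with miR-27b, and let-7e with miR-99b and miR-125a-5p. Over 51 pairs of genes within 10 kb and with unlike probes, the median difference in change was 0.427, against 0.639 for random pairs (one-sided permutation p = 0.0370). Like probe sequences are argued against as the whole cause, since that p, 0.0370, was obtained with all pairs sharing 7 bases in a row left out. Of the 19 such pairs with both members changed, 17 moved in a single direction, and miR-125a-3p went against both let-7e and miR-99b. A shared primary transcript is a candidate explanation, as a hypothesis.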

How the results depend on the processing

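All alternatives were set before the data were examined except the scaling to bright control features and the fit without slide 3, which were chosen after seeing the data. miR-155 kept its direction at each time and passed at 6 and 24 h in all 22 alternatives other than single arrays left out, with changes of 0.32 to 0.62 at 2 h, 1.60 to 2.16 at 6 h and 2.75 to 3.43 at 24 h. Where a result below changed, the cause was not tested.

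Under normexp, 2 miRNAs changed at 2 h, 6 at 6 h, and 14 list calls were made; the signs turned for miR-132 at 2 h (-0.0065) and, at 24 h, for miR-30e* (0.11), miR-582-5p (0.0376), miR-98 (0.0210), miR-342-3p (0.0900) and miR-137 (0.26), and on average for miR-1181 (0.0324) and miR-15a* (0.0381). With the percentile over all probes, 7 changed at 6 h, 109 differed in response between the times and 51 between control times. At 24 h that setting put miR-24 at -0.50, miR-31 at -0.47, miR-29b at -0.14, miR-181b at -0.55, miR-192 at -0.36, miR-107 at -0.59 and miR-140-3p at -0.46. With no scaling, 3 changed at 2 h and 6 at 6 h, with medians moved by 0.16 and -0.21; at 24 h miR-24 was at -0.42, miR-31 at -0.39, miR-29b at -0.0581, miR-107 at -0.51 and miR-140-3p at -0.38. Total gene signal gave -0.24 for miR-24, -0.18 for miR-31, -0.32 for miR-107 and -0.17 for miR-140-3p at 24 h. The authors' normalized values gave 7 at 6 h, and -0.25 for miR-31, -0.38 for miR-181b, -0.41 for miR-107 and -0.24 for miR-140-3p at 24 h. Bright control features gave -0.23 for miR-24, -0.20 for miR-31, -0.28 for miR-181b, -0.32 for miR-107 and -0.19 for miR-140-3p.

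With the floor doubled, 3 changed at 2 h and 4 list calls were made. With no filter, 53 of 851 changed on average, 40 differed in response and 17 of 48 list tests were called. With only miRNAs detected on all arrays (136), 1 changed at 2 h, 6 at 6 h and 4 list calls were made. The mean over probes gave 2 between control times. Array weights gave 10 at 2 h, 27 at 6 h, 120 differing in response and 3 between control times, miR-155 at 0.44 at 2 h (adjusted p = 0.00196), and miR-137 at 0.21 at 24 h. An estimated correlation left 2 list calls.

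The replicate block gave 6, 10 and 127 changed at 2, 6 and 24 h, 97 on average and 82 differing in response, and 5 list calls of 7 were kept. Of 193 named values, 185 kept their call under it, 2 lost it and 6 gained it, all named above. miR-155 at 2 h, not among the 193, gained its call too, as did miR-188-5p at 24 h, given in the next part, and no other call among these values changed. At 2 h miR-155 was 0.45 and passed with the replicate block (adjusted p = 0.0499), a random pair block (0.0298), a letter block (0.0402), only the 2 groups compared (0.00563) and without slide 3 (0.0228), with a range of 0.00196 to 0.992 over its 22 alternatives. The slide block and the replicate block with slide each gave 4 list calls. Without slide 3, 8, 13 and 106 changed at 2, 6 and 24 h.

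Leaving out each array in turn gave 5 to 8 changed at 2 h, 8 to 15 at 6 h, 101 to 121 at 24 h, 72 to 88 on average, 52 to 81 differing in response, 0 between control times (limma, 18 at an unadjusted p under 0.05 with all arrays) and 5 to 8 list calls. miR-155 then ranged from 0.42 to 0.50 at 2 h, 2.00 to 2.15 at 6 h and 3.20 to 3.54 at 24 h. Arrays set a limit for dim miRNAs, since 630 of 851 lay below detection on every array and their changes, if any, went unmeasured.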

Other observations

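The miRNAs in this part were chosen after their values were seen, as all tested members of 2 gene clusters, of the miR-320 family and of 2 hairpins. Along the miR-99b, let-7e and miR-125a transcript, miR-99b (-0.77 ± 0.11, n = 3 arrays per group), miR-125a-5p (-0.66 ± 0.11) and let-7e (-0.43 ± 0.10) fell at 24 h in 3 of 3 pairs. These 3 stayed lower and past the threshold in each of the 40 alternatives fitted. miR-125a-3p, from the other arm of the miR-125a hairpin, was higher by 0.46 ± 0.15 (adjusted p = 0.0159). It turned to -0.16 with the percentile over all probes and to -0.08 with no scaling, and did not pass without control 24 h replicate 3 (0.0868) or cytokine 24 h replicate 2 (0.0858), with adjusted p up to 0.831 over its alternatives. miR-32* rose by 1.33 ± 0.12 in 3 of 3 pairs over controls that all lay at the floor, and passed in all 39 alternatives that measured it, though its size followed the floor, with 0.33 at a doubled and 2.04 at a halved floor. Its guide miR-32 was at -0.34 (adjusted p = 0.315), and at 0.13 without cytokine 24 h replicate 3 and -0.67 without replicate 2, where it passed (0.0332).

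In the miR-532 cluster 5 of 8 tested miRNAs fell at 24 h, each in 3 of 3 pairs, namely miR-532-5p (-0.81 ± 0.10), miR-502-3p (-0.73 ± 0.15), miR-362-5p (-0.71 ± 0.12), miR-362-3p (-0.64 ± 0.10) and miR-532-3p (-0.52 ± 0.17). Under normexp none of the 5 passed in limma, and they stood at -0.04, 0.14, 0.09, 0.02 and 0.19 in that order. miR-532-3p also failed without cytokine 24 h replicate 3 (-0.39, adjusted p = 0.0708), with the floor doubled (-0.14), with no filter and without slide 3 (-0.40), and miR-502-3p with the floor doubled (-0.11) and with only the 2 groups compared. The other 3, miR-660 (-0.18), miR-501-3p (-0.08) and miR-188-5p (0.41), did not pass, and normexp put miR-660 and miR-501-3p at 0.08 and 0.31. miR-188-5p passed with the pairs as a block (0.0170) and without cytokine 24 h replicate 3 (0.75, adjusted p = 0.00464), and was at -0.10 with the percentile over all probes. miR-320a, miR-320b, miR-320c and miR-320d were higher by 0.33, 0.38, 0.50 and 0.43, but stood at -0.30, -0.24, -0.13 and -0.20 with the percentile over all probes and below 0 with no scaling, so no direction is given for that family. miR-221* was higher by 0.55 ± 0.12, and at -0.07 with the percentile over all probes; its guide miR-221 is described above.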
